A study of Mus musculus with 6 samples.

How the data were processed

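The data are 6 Affymetrix mouse expression arrays of cortical TRAP RNA from the Glt25d2 bacTRAP line DU9, backcrossed 3 to 5 generations from FVB onto C57BL/6. Per the labels' protocols, mice were given fluoxetine or vehicle in drinking water, tagged ribosomes were affinity purified, the RNA was extracted with Trizol and treated with DNase, and 15 ng was amplified in 2 cycles and labelled with biotin. The authors deposited 1 intensity per probe set and array, made with GCRMA per the submitters' processing notes and the series design text. GCRMA corrects background from probe sequence, normalizes between arrays and gives 1 value per probe set. Its version and settings are not given in the sources used here. The values run from about 2 upward on a linear scale, so they were read as intensities and not as log values. The design text says that replicates were averaged by condition, but the deposited table has 1 column per array, and these columns were used. It also speaks of an S100a10 transgene and of a published table of probe sets to keep. That table is not used here.

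Groups were taken from the title, source and treatment fields, 3 arrays per group. The description field of each sample names the opposite treatment, which the values cannot settle. Replicate numbers come from the titles. The labels call the samples independent purifications and biological replicates, and they do not say how many mice went into each. No pair of arrays looked like 1 library deposited under 2 names: log2 values correlated between 0.992 and 0.997, and the SD of the log2 difference was at least 0.23 for every pair. Exactly equal values were more frequent among the fluoxetine-titled arrays (1136 to 2204 probe sets per pair of arrays) than among the vehicle-titled ones (138 to 286) or across groups (93 to 637). At most 26 of them per pair of arrays reached an intensity of 50, and the cause was not tested.

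Of 45101 probe sets, 64 control probe sets were left out. Probe sets were kept where the mean of at least 1 group reached 50, which left 19073. This is a reading of the submitters' advice to filter at 50, whose wording leaves open whether 1 or both conditions must reach it. Names came from the platform annotation paired with the table: 34945 probe sets had 1 gene symbol, 932 had several and were left unnamed, and 9160 were not listed. Entrez identifiers were compared with a RefSeq gene table of assembly GRCm38.p6, which changed 0 symbols. That table was used for names and for the order of genes along chromosomes, and no coordinates are given. The probe set of highest mean stood for each of 10830 genes. Intensities of different probe sets share no common scale, so this is a rule of selection and not a ranking of abundance. No gene of the named-gene rule given below had a second probe set of opposite sign at an unadjusted p under 0.05. That check could seldom fail, since 121 of 19073 probe sets reached such a p in either direction. Many of these genes also had 1 probe set kept.

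Log2 intensities were fitted with lmFit and eBayes in limma 3.58.1 (R 4.3.3), fluoxetine-titled minus vehicle-titled, two-sided, with Benjamini-Hochberg adjustment over all probe sets kept. An adjusted p of 0.05 was the threshold, and a fold of at least 1.5 with an unadjusted p under 0.05 a descriptive one. Gene lists were tested with camera (preset correlation 0.01) on 1 probe set per gene, adjusted over the 33 of 35 lists with at least 5 measured genes. Fry and camera with an estimated correlation were run beside it. A list of 1 blood or choroid plexus marker and a list of 2 sex-linked genes were too short to test. The male-specific gene Eif2s3y lay between 834 and 1140 and the female-specific Xist at 10.5 or less on every array. Beside each list, members were also adjusted over the list alone. A list's median was set against 10000 random lists matched on mean expression. An interval given with a list or marker median comes from resampling the genes behind it. Such intervals measure spread between genes, which are not independent replicates.

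The replicate numbers pair the samples. Arrays of equal number deviated from their group means together, with correlations of 0.74, 0.60 and 0.50 for pairs 1, 2 and 3, while arrays of different number in different groups had between -0.59 and 0.26. The first principal component, 60.0% of the variance, separated the 2 arrays numbered 1 from the rest. The pairing comes from the titles' numbers and this check, since no label says what a number stands for. The fit without a block is the one reported, and the fit with the replicate number as a block is given where it changes a count or a call.

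The same code was tested on simulated data: 20 sets of arrays with the real means, pair effects and residual spread, and 200 of 19073 probe sets changed. Changed probe sets were drawn from those with a mean log2 intensity above 7. Without the block, 0% of 1.5-fold, 23.7% of 2-fold and 89.2% of 4-fold changes were recovered, with 0.2% false calls. With the block, 48.9%, 95.2% and 100% were recovered, with 5.26% false calls. A list shifted by 0.3 on the log2 scale was called by camera in 20 of 20 runs in both fits. With an estimated correlation it was called in 14 of 20 runs without the block and in 0 of 20 with it, so a loss of a call in the latter setting carries little weight. Simulated noise was independent between genes, which favours camera with a preset correlation.

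The groups, tests, gene lists, named-gene rule and most alternatives were fixed before the data were examined. The alternatives were other filters on dim probe sets, an offset of 16, renormalization, an intensity trend, array weights, the replicate block as a fixed or random term, each array left out, other choices of probe set and other set tests. Leaving out each pair, and the estimated correlation and fry in the blocked fit, were added after the data were seen. Named genes were the up to 10 per direction with the largest difference past the threshold, or else of smallest unadjusted p with no overlap between groups and a fold of at least 1.5 (9 higher and 1 lower existed). To these were added up to 4 members of each list past camera, a fixed set (Colgalt2, S100a10, the serotonin receptors kept, Bdnf, Fos and Arc) and the 2 members of highest mean intensity in each list of other cell types. This named 57 genes.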

Results

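Ribosome-bound RNA was profiled from 1 class of cortical neuron in mice that drank the antidepressant fluoxetine or its vehicle. The mice carried the DU9 line of the Glt25d2 bacTRAP transgene, in which the regulatory region of Glt25d2 (now named Colgalt2) drives a tagged ribosomal protein in pyramidal cells of cortical layer 5. Translating ribosome affinity purification (TRAP) pulls down the tagged ribosomes, so the RNA on the arrays is enriched for messages being translated in those cells. The treated mice received 0.167 mg/ml fluoxetine in 1% saccharine and the controls 1% saccharine alone, for 15 to 18 days. There were 6 Affymetrix arrays, 3 per treatment, each hybridised with RNA from a separate cortical purification. The median intensity per array lay between 23.03 and 23.45, and between 41.4% and 41.8% of probe sets reached an intensity of 50. The number of arrays limits the precision of every difference below.

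The direction of every difference between the treatments rests on which label is read. The title, source and treatment fields of each sample name 1 treatment, and the short description field names the opposite one. Groups follow the first 3 fields here, and arrays are called fluoxetine-titled or vehicle-titled for that reason. If the description were right, the sign of every treatment difference below would turn and no p-value would change.

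The comparison of fluoxetine-titled with vehicle-titled arrays asks how 15 to 18 days of the drug alter the messages translated in layer 5 pyramidal cells. The translated messages of the 2 sets of arrays were close to each other. Of 19073 probe sets, 94.0% had a 95% confidence interval of the difference that lay within 2-fold in either direction, and the median standard error was 0.18 on the log2 scale. No probe set passed an adjusted p of 0.05 in limma, where the smallest adjusted p was 1 and 121 probe sets had an unadjusted p under 0.05, against 954 given by chance. With the replicate number as a block, limma again gave 0 probe sets, with a smallest adjusted p of 0.993 and 767 probe sets at an unadjusted p under 0.05. The median standard error was then 0.11. The fit without the block counts variance between pairs as noise, which widens its standard errors and raises its p-values. All 3 fluoxetine-titled values lay above all 3 vehicle-titled values for 177 of 10830 genes and below them for 214, together 3.61%, where chance gives 10% if the arrays are not paired. Within the pairs of arrays that share a replicate number, 10.9% of genes were higher and 13.1% lower in all 3, where chance gives 1 in 8 for each direction.

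A difference of at least 1.5-fold with an unadjusted p under 0.05 was found for 18 probe sets, 13 of them higher and 5 lower in the fluoxetine-titled arrays. The 5 were those of Cdsn, Eno4, Klhl11, Pigt and Gm19439, of which all but Cdsn are named after their values were seen. For Eno4 it was not the probe set of highest mean. That one had 198.5, 130.6 and 76.1 in the fluoxetine-titled and 154.5, 159.3 and 187.3 in the vehicle-titled arrays. For Pigt the probe set of highest mean had 66.7, 43.3 and 39.5 against 64.1, 113.7 and 67.2, highest on vehicle array 2. In place of 18, the count was 41 with the replicate block, 31 of them higher, and between 31 and 142 with 1 array left out, the highest without fluoxetine array 1. The genes that follow differed by at least 1.5-fold with no overlap between the groups, and are given as values because none passed the adjusted threshold. Insulin-like growth factor 1, Igf1, had an intensity of 55.9 ± 4.02 (SD, n = 3) in the fluoxetine-titled and 30.5 ± 4.74 (n = 3) in the vehicle-titled arrays, a log2 difference of 0.89 ± 0.16 (SE). In the fit without the block, Igf1 was the single gene of any list that passed when adjusted over the list alone (adjusted p = 0.0147 among 21 neurotrophin, growth factor and CREB signalling genes), and it did not pass over all genes tested. With the block, Acta2, Pdgfrb and Ddit4 of other lists passed too. Adjustment over a list alone does not correct for the number of lists. With values under 50 set to 50 the log2 difference of Igf1 was 0.16 and the list call was lost (adjusted p = 0.955), since all 3 vehicle-titled values lay below 50. The secreted Wnt inhibitor Wif1 had intensities of 50.8 ± 4.53 and 30.4 ± 2.75, and the log2 difference lay between 0.72 and 0.77 in all 3 pairs of arrays that share a replicate number. The eicosanoid-metabolising reductase Ptgr1 had intensities of 95.4 ± 8.12 and 60.1 ± 10.1, and the laminin chain gene Lamb2 100.4 ± 11.8 and 66.5 ± 4.63. The log2 difference was 0.82 for the transcription factor gene Atoh7, 0.75 for Lpcat2, 0.62 for the Fc receptor gene Fcgr1, 0.68 for smooth muscle actin, Acta2, and 0.59 for Pla2g7, whose unadjusted p was 0.0617. For Igf1, Ptgr1, Lamb2, Acta2, Lpcat2, Fcgr1 and Pla2g7 the difference was largest in pair 3 (1.16, 0.98 and 1.13 for the last 3). That is the pair in which glial markers differed, as described below. For Wif1 and Atoh7 it was smallest there (0.72 and 0.32). Whether RNA of other cell types contributes to these differences was not tested. In the other direction, the corneodesmosin gene Cdsn had intensities of 34.7 ± 3.23 in the fluoxetine-titled and 55.4 ± 6.25 in the vehicle-titled arrays, a log2 difference of -0.67 ± 0.15. The mean of 1 of the groups lay below an intensity of 50 for Igf1, Wif1, Atoh7, Lpcat2 and Cdsn.

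**Figure D1:**
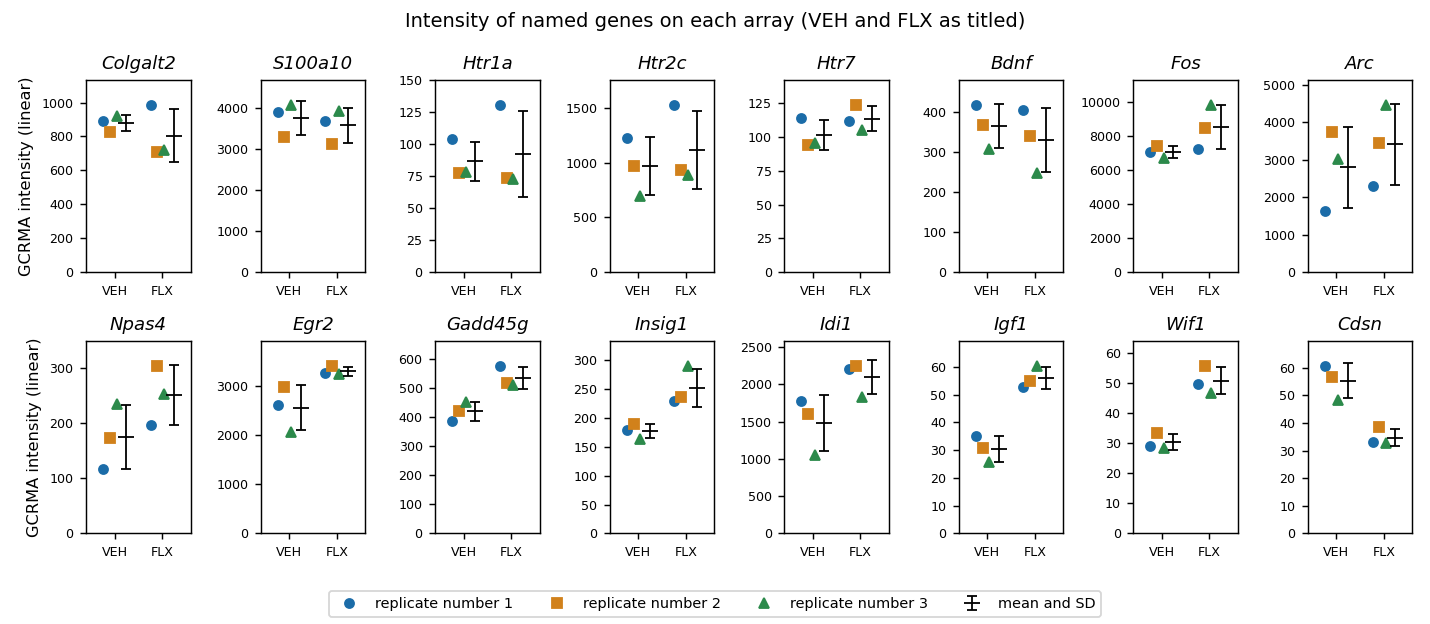
Intensity (GCRMA, linear scale, axes from 0) of 16 named genes on the 3 vehicle-titled (VEH) and 3 fluoxetine-titled (FLX) arrays, with the mean and SD of each group, and a separate scale for each gene. Symbols mark the replicate number. The groups do not overlap for Igf1, Wif1, Cdsn, Egr2, Gadd45g, Insig1 and Idi1, and they overlap for Colgalt2, S100a10, the serotonin receptors, Bdnf, Fos, Arc and Npas4.

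The gene that defines the labelled cells, Colgalt2, had an intensity of 804.7 ± 157 in the fluoxetine-titled and 879.0 ± 46.1 in the vehicle-titled arrays (n = 3 each). Across 13 measured markers of layer 5 neurons that project below the cortex, Colgalt2 among them, the median log2 difference was -0.075 (camera adjusted p = 0.439), and without pair 1 it was -0.18 (adjusted p = 0.0265). S100a10, which encodes the serotonin receptor partner p11 and is itself expressed in a set of layer 5 cells, had a log2 difference of -0.074 ± 0.15, and its sign was negative in all 3 pairs. Serotonin receptor messages did not pass the test as a list or as genes. Of 13 receptor genes with a probe set, 7 reached the intensity filter, and their list had a median log2 difference of 0.045 (camera adjusted p = 0.72). Htr2c had intensities of 1114 ± 358 and 964.9 ± 264. The log2 difference was 0.045 ± 0.26 for Htr1a, -0.23 ± 0.27 for Htr1b, -0.047 ± 0.16 for Htr1f, 0.20 ± 0.28 for Htr2c, 0.065 ± 0.17 for Htr4, -0.022 ± 0.18 for Htr5a and 0.17 ± 0.14 for Htr7. Htr1d, Htr2b, Htr3a, Htr3b, Htr5b and Htr6 stayed below an intensity of 50 in both groups, with 41.6 for Htr3a the highest. The 6 measured genes of the p11 pathway, 5 of which stand in other lists too, had a median of -0.057 (camera adjusted p = 0.743). The neurotrophin gene Bdnf had intensities of 331.0 ± 79.6 and 364.6 ± 54.7, a log2 difference of -0.16 ± 0.22. Its interval, from -0.66 to 0.35, contains 0 and leaves out a 2-fold difference. With 1 array left out, the sign of the difference turned in at least 1 case for Htr1a, Htr1b, Htr1f, Htr2c, Htr4, Htr5a, S100a10 and Bdnf, among them Htr1a and Htr2c without fluoxetine array 1 (to -0.23 and -0.051) and Htr5a without vehicle array 1 (to 0.081).

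The list of immediate early genes lay slightly higher in the fluoxetine-titled arrays, as did the vessel markers described below. Of 29 measured immediate early genes, which neurons induce within minutes to hours of firing, 23 had a positive difference. The 6 with a negative one were Jund (-0.29), Ptgs2 (-0.18), Homer1 (-0.11), Egr1 (-0.064), Egr4 (-0.012) and Dusp5 (-0.0017). The list median was 0.17 on the log2 scale, and 14 genes were higher and 0 lower in all 3 pairs. The pair medians were 0.15, 0.10 and 0.17. The list ranked above other genes in camera (adjusted p = 3.56e-07), a call that was lost with an estimated correlation (adjusted p = 0.26 with an estimated correlation). No member passed over all genes and none passed adjusted over the list alone. Npas4, a transcription factor gene that depends on neuronal activity, had intensities of 251.8 ± 54.0 and 175.3 ± 58.7. Egr2 had 3293 ± 92.2 and 2547 ± 458, Gadd45g 534.5 ± 36.8 and 419.8 ± 32.7, and the growth-arrest gene Btg2 81.8 ± 20.9 and 58.8 ± 16.6. Fos and Arc, the most used activity markers, had log2 differences of 0.26 ± 0.15 and 0.32 ± 0.36. Arc was lower in the fluoxetine-titled array of pair 2 and higher in the other 2 pairs.

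Genes of cholesterol synthesis and uptake were placed the same way. Of 20 measured genes, 19 had a positive difference, with a median of 0.18 and pair medians of 0.25, 0.073 (-0.042 to 0.10) and 0.22, and 10 were higher in all 3 pairs against 1 lower. Their median was lowest on vehicle array 3 (-0.23, against -0.031 to 0.15 on the others), the array lowest in glial markers, and leaving that array out gave the smallest list median of any alternative, 0.086. The list ranked above other genes in camera (adjusted p = 3.56e-07), and this call too was lost with an estimated correlation (adjusted p = 0.468 with an estimated correlation). No member passed over all genes and none adjusted over the list alone. Insig1, which holds the sterol sensor in the endoplasmic reticulum, had intensities of 252.4 ± 33.4 and 177.8 ± 12.8. Idi1, an isomerase of the isoprenoid pathway, had 2097 ± 226 and 1477 ± 377. The lanosterol demethylase gene Cyp51 had a log2 difference of 0.27 ± 0.15 and mevalonate kinase, Mvk, one of 0.19 ± 0.12.

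Genes of the mitochondrial respiratory chain and ATP synthase lay slightly lower in the fluoxetine-titled array of pair 3. Of 72 measured genes, 58 had a negative difference, with a median of -0.076. The list ranked below other genes in camera (adjusted p = 0.00692), with adjusted p = 0.88 with an estimated correlation. The pair medians were -0.019 (-0.043 to 0.018), -0.0069 (-0.049 to 0.017) and -0.16 (-0.19 to -0.14), and pair 3 is also the pair in which glial markers differed, by a median of 0.56. Cox5b had intensities of 26900 ± 712 and 29950 ± 2530, a log2 difference of -0.15 ± 0.13, and the differences for Uqcrb, Cox7a2 and Atp5mpl were -0.16 ± 0.13, -0.16 ± 0.14 and -0.25 ± 0.21. Unlike the list, each of these genes had its largest difference in pair 1. For Cox5b, Uqcrb, Cox7a2 and Atp5mpl it was -0.25, -0.24, -0.20 and -0.45 there, against -0.12, -0.12, -0.17 and -0.42 in pair 3. No member passed over all genes or adjusted over the list alone. The call was lost under quantile normalization (adjusted p = 0.148, median -0.056), without pair 3 (adjusted p = 0.943, median -0.023), and without any of vehicle arrays 1 and 3 and fluoxetine arrays 2 and 3 (adjusted p from 0.335 to 0.718, medians from -0.055 to -0.010).

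**Figure D2:**
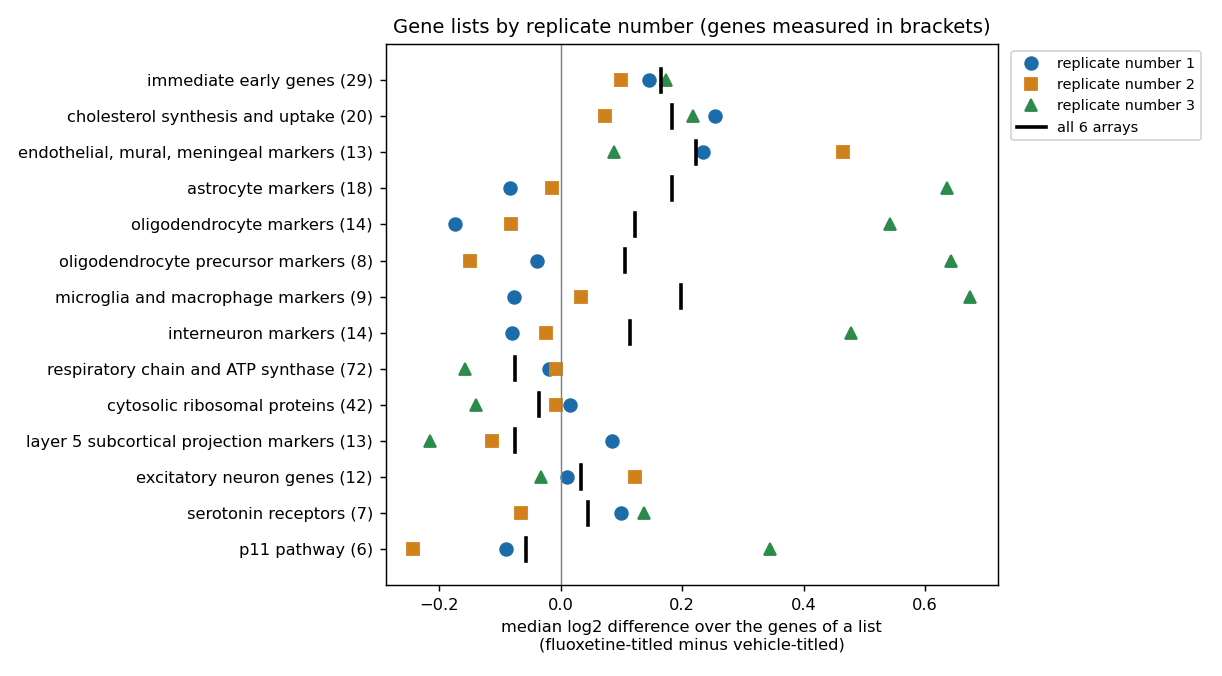
Median log2 difference (fluoxetine-titled minus vehicle-titled) over the genes of 14 lists, within each pair of arrays that share a replicate number (symbols) and over all 6 arrays (black bars). The medians of immediate early and cholesterol genes lie above 0 in all 3 pairs, and the glial and interneuron lists lie far above 0 in pair 3 alone.

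Markers of cell types other than the labelled neurons differed between arrays. Of 18 astrocyte markers, 16 were higher in the fluoxetine-titled arrays, with a median log2 difference of 0.18, and the list passed camera (adjusted p = 0.00134), with adjusted p = 0.88 with an estimated correlation. That difference came from 1 pair, since the pair medians were -0.083, -0.014 and 0.64. Without vehicle array 3 the median was -0.075 and without pair 3 it was -0.022, and the call was also lost without fluoxetine array 2 (adjusted p = 0.334, median 0.099). The astrocyte genes Slc4a4 and Fgfr3 had log2 differences of 0.97 and 0.71 in pair 3, and of -0.055 and 0.21 in pair 1. Ndrg2 and Ntsr2 had 0.74 and 0.89 in pair 3. Oligodendrocyte, oligodendrocyte precursor, microglia and interneuron markers had the same shape, with medians of 0.54, 0.64, 0.67 and 0.48 in pair 3 and medians between -0.17 and 0.033 in pairs 1 and 2. None of these 4 lists passed camera (adjusted p = 0.439, 0.463, 0.439 and 0.212) over all arrays. Without vehicle array 2 the oligodendrocyte, precursor and interneuron lists passed, with medians of 0.34, 0.30 and 0.29 (adjusted p = 1.83e-05, 0.00253 and 0.000666), as they did without pair 2, with 0.18, 0.25 and 0.16 (adjusted p = 0.00898, 0.0266 and 0.0288). Without vehicle array 3 the oligodendrocyte list passed in the opposite direction (-0.23, adjusted p = 0.00475). Microglia markers passed without vehicle array 1 (0.38, adjusted p = 0.0434) and without fluoxetine array 3 (0.33, adjusted p = 0.0209). The intensity of the myelin gene Cnp was 18150 ± 1980 and 16710 ± 4600, that of the GABA-synthesising enzyme gene Gad1 17750 ± 1990 and 16660 ± 2870, and that of the astrocyte gene Aldoc 14440 ± 1620 and 13860 ± 3920. For Clu, Mbp, Cck, Olig1, Sox10, Ctss and Csf1r the log2 difference lay between -0.12 and 0.20, with standard errors from 0.21 to 0.40.

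Vessel-associated genes had a positive median difference in each pair. Of 13 endothelial, mural and meningeal markers, 12 had a positive difference, with a median of 0.22 and pair medians of 0.23, 0.47 and 0.088, the last with an interval from -0.12 to 0.35, and 7 of the 13 were higher in all 3 pairs. The list passed camera (adjusted p = 1.44e-04), with adjusted p = 0.26 with an estimated correlation, and the call was lost without fluoxetine array 1 (adjusted p = 0.0954, median 0.098). No member passed over all genes. In the fit without the block 0 passed adjusted over the list alone, and with the block 2 did, Acta2 and Pdgfrb. Acta2 of smooth muscle had intensities of 485.7 ± 75.6 and 303.8 ± 57.6, the pericyte receptor gene Pdgfrb 255.1 ± 90.4 and 189.4 ± 57.7, the tight junction gene Cldn5 629.4 ± 80.6 and 524.5 ± 202, and the transporter gene Abcb1a 95.5 ± 19.2 and 72.2 ± 13.8. By array, the list median was lowest on vehicle arrays 2 and 3 (-0.24 and -0.23) and highest on fluoxetine array 1 (0.30). Cldn5 had 316.9 on vehicle array 2 against 536.1 to 720.6 on the others, while Pdgfrb was lowest on vehicle array 1 (145.0). Ptgds and Slc2a1 had log2 differences of 0.086 ± 0.24 and 0.11 ± 0.21. Clic6, the 1 measured marker of blood or choroid plexus, had a difference of -0.15 ± 0.20.

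**Figure D3:**
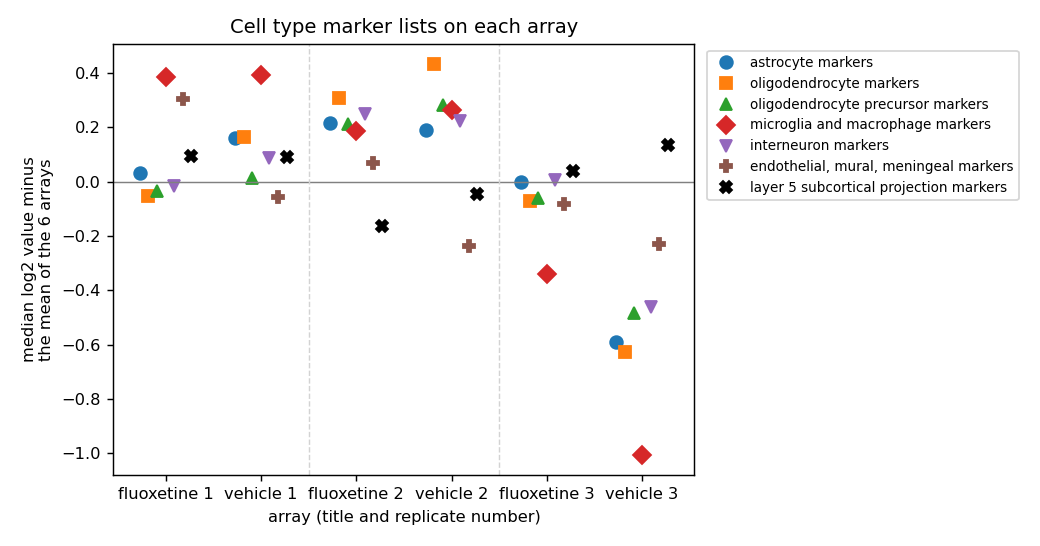
Median log2 value of 7 marker lists on each array, relative to the mean of the 6 arrays for each gene. Vehicle array 3 is the lowest in the astrocyte, oligodendrocyte, oligodendrocyte precursor, microglia and interneuron lists, with medians from -0.46 to -1.01.

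The other lists did not pass camera over all arrays. Median log2 differences were 0.046 for other cortical projection neuron markers (with Rasgrf2 at -0.26 ± 0.23), 0.033 for genes of excitatory neurons and 0.072 for markers of striatum, hippocampus and thalamus (with Penk at -0.21 ± 0.22 and Tac1 at 0.0011 ± 0.30), with camera adjusted p of 0.52, 0.72 and 0.474. Among receptors and channels they were -0.011 for glutamate receptors, 0.021 for GABA receptors, -0.015 for other monoamine, acetylcholine, opioid and cannabinoid receptors, -0.0071 for potassium channels and 0.019 for sodium and calcium channels. Genes of the synapse had medians of -0.0038 (postsynaptic) and 0.011 (presynaptic), cytoskeleton and axon growth genes -0.033, neuropeptides -0.024, neurotrophins and growth factors -0.054 and G-protein signalling regulators -0.034. For these 11 lists the camera adjusted p lay between 0.465 and 0.969. Circadian, glucocorticoid response, heat shock, chromatin, ribosomal protein and interferon lists had medians of 0.039, 0.0059, -0.013, 0.012, -0.035 and 0.0046, with adjusted p of 0.874, 0.731, 0.752, 0.72, 0.439 and 0.72. With the block, 1 glucocorticoid response gene, the stress-induced Ddit4, passed adjusted over the list alone, with a log2 difference of 0.60 and a positive sign in all 3 pairs. Wnt, Notch and TGF-beta genes had a median of 0.048, a mean of 0.18 and an adjusted p of 0.064, and passed with array weights (0.097, adjusted p = 0.0295), without pair 1 (0.13, adjusted p = 0.0298) and with the mean of all probe sets (0.062, adjusted p = 0.0317). The highest difference in that list, 1.34, raises its mean but does not alone account for the gap to its median. Notch1 had an intensity of 1148 on fluoxetine array 1 against 69.4 to 179.3 on the others. Notch2 and Notch3 were far brighter on that array too, with 1768 and 124.4. Ribosomal protein genes passed without vehicle array 2 (-0.10, adjusted p = 0.000182) and without fluoxetine array 1 (-0.13, adjusted p = 0.00777), neuropeptides without vehicle array 3 (-0.15, adjusted p = 0.00309) and GABA receptors without fluoxetine array 3 (0.17, adjusted p = 0.0247). Markers of striatum, hippocampus and thalamus passed without vehicle array 2 (0.23, adjusted p = 0.00253) and without pair 2 (0.22, adjusted p = 0.0288). Median, mean and camera direction differed in sign for the neurotrophin, glutamate receptor, postsynaptic, presynaptic, interferon and G-protein lists, all with medians between -0.054 and 0.011.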

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

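The additional settings that leave out a pair, and those that join another set test with the block, were chosen after the data were seen. The count of 0 probe sets past an adjusted p of 0.05 held in every alternative run, which were the filters, scalings, variance models, blocks, each array or pair left out, a test with unequal variances and a threshold of 0.10. The 18 probe sets at 1.5-fold and an unadjusted p under 0.05 became 10 where both group means had to reach 50, 8 with values under 50 set to 50, 6 on the log2(value + 16) scale, 51 with no filter, 37 with array weights, 41 with the replicate block and 38 with it as a random term. With 1 array left out that count lay between 31 and 142, with 142 without fluoxetine array 1, 70 without vehicle array 1, 55 without vehicle array 2, 38 without fluoxetine array 3, 33 without vehicle array 3 and 31 without fluoxetine array 2. It was 112, 38 and 44 without pairs 1, 2 and 3. Fewer arrays leave fewer degrees of freedom, and the cause of the rise without pair 1 was not tested. Of the 18, the block kept 18 and the offset kept 6.

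The 5 lists past camera were 4 under quantile normalization, 6 with array weights, 9 without pair 2, 3 without pair 3, and 0 with an estimated correlation, with fry, and with either in the blocked fit. Leaving out 1 array gave between 3 (without fluoxetine array 2) and 10 lists (without vehicle array 2). The immediate early and cholesterol lists kept their call in 22 of 26 alternatives each, with medians from 0.11 to 0.23 and from 0.086 to 0.24. They lost it under the other 4, the estimated correlation and fry with and without the block. The replicate block alone changed no list's call. Among the 28 lists not past the threshold, 19 of 728 values passed it under some alternative, and 0 of 1239 values of named genes did.

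Of 2097 list and gene values under alternatives, 156 had the opposite sign to the reported value, 92 of them with 1 array left out. Values near 0 turn easily, so the values printed here are the 37 that moved by more than 1 SD between the 3 pairs or belong to a list past the threshold in either setting. That limit was chosen after a stricter one had listed more values. The astrocyte median went from 0.18 to -0.075 without vehicle array 3 and to -0.022 without pair 3, and the oligodendrocyte median from 0.12 to -0.23 without vehicle array 3 (adjusted p = 0.00475). With 1 array left out, the astrocyte median ranged from -0.075 to 0.38 and the oligodendrocyte median from -0.23 to 0.34. The GABA receptor median was -0.020 with array weights and ranged from -0.080 to 0.17 with 1 array left out. The same ranges were -0.054 to 0.054 for neurotrophins, -0.090 to 0.091 for glutamate receptors, -0.072 to 0.079 for postsynaptic, -0.082 to 0.063 for presynaptic, -0.075 to 0.021 for cytoskeleton, -0.20 to 0.070 for interferon, -0.041 to 0.025 for heat shock and -0.097 to 0.10 for chromatin genes. For single genes they were -0.23 to 0.19 for Htr1a, -0.051 to 0.39 for Htr2c, -0.16 to 0.081 for Htr5a, -0.068 to 0.27 for Slc2a1, -0.17 to 0.022 for S100a10 and -0.32 to 0.037 for Bdnf. Without pair 1 the median was 0.048 for other monoamine, acetylcholine, opioid and cannabinoid receptors and 0.073 for glutamate receptors. For heat shock genes it was 0.016 without pair 2 and 0.0054 without pair 3, and for chromatin genes -0.029 without pair 3. The cause was not tested for these. The intensity filter of 50 limits the dimmest genes, where the offset and the floor shrink differences such as those of Igf1, Wif1 and Cdsn.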

Other observations

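The arrays that share replicate number 1 differed from the other 4 far more than the treatments differed from each other, and this contrast was singled out after the data were seen. In limma with the treatment as a term, 2910 of 19073 probe sets (15.3%) passed an adjusted p of 0.05, 1187 higher and 1723 lower in the arrays numbered 1, and 2907 did after quantile normalization. Chromatin and DNA methylation regulators had a median of -0.30 there without passing (camera adjusted p = 0.0694, and adjusted p = 0.775 with an estimated correlation). Postsynaptic and cytoskeleton genes had -0.21 and -0.14 (camera adjusted p = 0.0694 for each) and neuropeptides 0.41 (camera adjusted p = 0.0766), also without passing. Presynaptic vesicle release genes had a median of -0.13 (adjusted p = 0.0149, and adjusted p = 0.875 with an estimated correlation). Mitochondrial respiratory chain genes had 0.20 (adjusted p = 0.00524, and adjusted p = 0.931 with an estimated correlation), and cytosolic ribosomal proteins 0.20 (adjusted p = 0.0193, and adjusted p = 0.943 with an estimated correlation). Among the leading genes, chosen after their values were seen, the log2 difference was -2.89 ± 0.16 for the postsynaptic scaffold gene Dlgap2, -2.55 ± 0.14 for the deubiquitinase gene Usp48, -2.52 ± 0.26 for Zc3h13, 1.22 ± 0.18 for the respiratory chain gene Uqcr10 and 1.53 ± 0.32 for Id1.

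Single arrays held a few genes far from the other 5, also named after their values were seen. On fluoxetine array 3, the nuclear noncoding RNA Malat1 had an intensity of 1691 against 50.2 to 348.9 elsewhere, and the noncoding RNAs Meg3 and Miat had 600.0 and 260.4 against at most 191.9 and 93.2. On fluoxetine array 1, Notch1 had 1148 against 69.4 to 179.3, Notch2 1768 against 61.9 to 250.6, Notch3 124.4 against 16.3 to 52.7, and Ltbp1 154.5 against 15.5 to 28.9. These 4 genes encode proteins with repeated EGF-like domains, and the second probe set of Notch1 had 39.7 on that array against 24.8 to 34.6. On vehicle array 3, 17 genes had less than 0.5 of the next lowest array's intensity, 4 of them in the glial lists, among them Csf1r with 343.6 against 691.6 to 1096 and Laptm5 with 211.2 against 443.6 to 772.8. On the arrays numbered 1, the middle to 3′ ratio of the actin control was 0.222 and 0.206 against 0.258 to 0.284 on the rest. Its 5′ to 3′ ratio was not lower there (0.154 and 0.121 against 0.118 to 0.133), and neither was that of Gapdh (0.542 and 0.420 against 0.324 to 0.427). The hybridization control spikes were dimmer on the fluoxetine-titled array of each pair, by a log2 difference of -0.48, -0.11 and -0.18.

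In the patterns that follow, the strain and transcript-position tests and the split counts of the 2 list medians were set before their results were seen, the reference for the position test was added later but before its value was seen, and the other tests were chosen after. The first pattern is that the arrays numbered 1 stand apart, and the labels name no group or treatment that these 2 arrays share. Residual FVB chromosome segments would place the differing genes side by side, but neighbouring pairs of differing genes were 1.1 times as many as in permuted gene order (0.97 to 1.25), which argues against segments as the whole cause. Glial RNA stays open: the median of 48 glial markers was 0.16, with an interval from 0.036 to 0.36. That median lay below the median size of the difference over all genes (0.22), while the interval reached above it. The whole interval lay below the median size for the probe sets that passed (0.71), which selection raises. The list medians were 0.12 for astrocyte, 0.017 for oligodendrocyte, -0.068 for precursor and 0.54 for microglia markers. Of 4 criteria tried for glial RNA, the first, used here, left it open, the next 2 argued against it and the last argued against all but microglia. A different signal along transcripts, from RNA integrity or amplification, remains a candidate explanation: across 1050 genes with 2 probe sets and a difference in at least 1, the differences of the 2 probe sets correlated with an r of 0.13 (0.078 to 0.18, across genes, which are not independent replicates), against 0.64 (0.60 to 0.68) for as many genes between the arrays numbered 3 and 2, and alternative transcripts that only 1 of 2 probe sets detects stay open too.

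The second pattern is that glial marker lists lay higher in the fluoxetine-titled arrays. A higher glial level with fluoxetine in every pair is argued against, since the larger of the medians of 48 glial markers in pairs 1 and 2 was -0.029 (-0.084 to 0.039), against 0.56 (0.48 to 0.71) in pair 3. Whether vehicle array 3 alone held less RNA of other cell types stays open: 5 of 6 lists had their lowest median there, which restates the pattern, and microglia markers were low on fluoxetine array 3 too (-0.34, against 0.19 to 0.39 on the arrays of pairs 1 and 2). The TRAP purification is meant to remove such RNA, and how much is carried over may vary by purification. Endothelial and mural markers had another shape, with their largest difference in pair 2, so 1 change in carry-over would not account for both.

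The third pattern is that immediate early and cholesterol synthesis genes lay higher in the fluoxetine-titled arrays. Glial RNA is argued against as the whole cause of both by pairs 1 and 2, where glial markers were not higher. Over these pairs the median was 0.15 (0.034 to 0.19) for immediate early genes and 0.16 (0.086 to 0.22) for cholesterol genes. The cholesterol value rested mainly on pair 1 (0.25), with 0.073 (-0.042 to 0.10) in pair 2. The cholesterol median was also lowest on vehicle array 3 (-0.23), the array lowest in glial markers. A glial share of the cholesterol difference therefore stays open. A shift of all genes of like brightness is argued against, as both medians lay above all 10000 matched random lists (percentile 100). Camera had already ranked both lists above other genes in these data, so the percentile adds no support for a treatment effect. The astrocyte list, whose difference came from 1 pair, had percentile 100 too. RNA of vessel cells stays open, since vessel markers were higher in the same arrays (0.23, 0.47 and 0.088 by pair), and so does a hybridization difference, since the control spikes differed by -0.48, -0.11 and -0.18. A response of the neurons to fluoxetine, or a difference in handling at collection, could each account for the first list, neither was tested, and both calls were lost with an estimated correlation.

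The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. For probe sets past an adjusted p of 0.05, all 10 gave as many as the real split, with 0 there and 0 as the highest other. At the descriptive threshold the real split gave 18 and the highest other 1099, and 9 of 10 gave as many. The splits that keep both arrays numbered 1 together gave 771 to 1099, which points to the structure of the samples described above. For lists past camera the real split gave 5 and the highest other 12, with 6 of 10 giving as many. Among the 4 splits that part all 3 pairs, the other 3 gave 15 to 27 probe sets and 3 to 9 lists. The immediate early and cholesterol lists had the smallest camera p of the 33 lists in the real split. A high rank of that split for their medians is therefore partly built in. The immediate early median was 0.17 in the real split and at most 0.12 in size in another, with 1 of 10 as large. The cholesterol median was 0.18 against a highest other of 0.19, with 2 of 10 as large, and that other split keeps pairs 2 and 3 together. Camera called the cholesterol list there too (adjusted p = 6.7e-05). The split of fluoxetine arrays 1 and 3 with vehicle array 2 parts all pairs. In it camera called the cholesterol list (adjusted p = 0.00039) and the immediate early list (adjusted p = 0.0238). The immediate early list also passed, with a negative median, for both arrays numbered 1 with vehicle array 3 (adjusted p = 0.0272).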
